A study of Mus musculus with 24 samples.

How the data were processed

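RNA was measured in 24 libraries of thoracic aorta from adult male wild-type C57BL/6 mice aged 10 to 12 weeks. The labels place 8 libraries in each of 3 groups, fed for 3 weeks with chow holding celecoxib at 100 mg/kg/day, chow holding rofecoxib at 50 mg/kg/day, or chow with no drug. Tissue was collected at zeitgeber time 11, counted in hours from lights on. Per the labels' protocols, polyA RNA was made into TruSeq libraries with 13 PCR cycles, and library construction took 3 days. The day on which each library was made is not given in the sources used here, so a library batch could not be set against the groups. Each sample title also carries a number of its own. These numbers run in a separate block per group, with the controls set apart after both drugs. What they mark is not stated, so an order or batch that follows them cannot be told apart from the groups. The series' design text calls the 8 libraries of a group biological replicates; no label names the animal behind a library. If some libraries shared an animal, the p-values would measure only the spread between these samples.

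Per the submitters' processing notes, CASAVA 1.8.2 and STAR 2.5.1b were used with the mm9 genome build. The counting tool and the gene annotation are not given in the sources used here. The authors deposited counts per gene as whole numbers, in 1 table with 25941 genes that carry Ensembl identifiers, symbols and mm9 coordinates. Of these genes, 1954 were at 0 in every library, and no gene on chromosome M was in the table. The library totals of the deposited counts ran from 21652432 to 21687906, a range of 0.164%. Raw totals rarely lie so close together, so the totals had been made nearly equal before deposit by a step that is not given in the sources used here. If reads were drawn at random, counts stay counts and only precision is lost, but if counts were scaled and rounded, the spread that edgeR assumes for counts would not hold. After the data had been seen, the number of genes at each count from 3 to 60 was set against the mean of its neighbours, as a squared difference over its Poisson variance. This averaged 1.07 over the 24 libraries (0.737 to 1.90), 1.16 after a random draw of the counts, and 7.77 to 96.8 after scaling them by 0.5 to 1.5 and rounding. Of the smaller factors, 0.3 gave 4.90 and 0.1 gave 4.47, with the lowest library at 3.10 and 3.19, above every deposited library. A factor of 0.05 gave 2.09 (1.18 to 3.13), 0.2 gave 1.21 and 0.02 gave 1.24, which overlap the deposited libraries, so scaling by these 3 factors was not excluded, and other factors were not tried. Without stated strand use, reads of overlapping or antisense genes could not be told apart, and genes with near-identical copies, such as the ribosomal proteins and some actins, may share reads.

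Genes were tested with edgeR 4.0.16 (R 4.3.3) on the deposited counts. Low-count genes were removed with filterByExpr, which left 14451 genes, and library sizes were scaled with TMM factors (0.959 to 1.03). A quasi-likelihood model with robust dispersion was fitted to all 24 libraries with 1 mean per group, which left 21 residual degrees of freedom. The 3 contrasts between groups were tested, and p-values were adjusted by Benjamini-Hochberg over the genes tested. A gene is called at an adjusted p under 0.05, with no minimum fold. Log2 fold changes are given ± SE, where the SE is the absolute log2 fold change divided by the square root of the quasi-likelihood F. Levels are TMM-scaled CPM, counts relative to library size, given as mean ± SD over 8 libraries.

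Gene groups were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01. Of the 39 lists of pathway genes and cell type markers, 37 had at least 5 genes tested. P-values were adjusted over these lists within a comparison. Each passing list is given with the adjusted p that camera reached with an estimated correlation, which takes the correlation between genes from these libraries. The number of called members is given over all genes tested and again adjusted over the list alone. A list's score is the mean log2 CPM of its members in a library, and scores were compared between groups with two-sided exact permutation tests.

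The lists, the tests, most alternatives and the rule for named genes were fixed before the data were examined. The rule took, per comparison, the 6 genes with the smallest p in each direction among the called genes. It added the 4 largest fold changes in each direction with an average log2 CPM of at least 1, up to 4 called members of each list and the 3 leading members of each passing list. It also took Ptgs1, Ptgs2, Ptgis, Ptges, Ptgir, Tbxas1, Nos3, Ren1 and Agtr1a. Ren1 was not among the genes tested. The text names part of the genes so chosen.

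Transcript GC content came from GENCODE M21 on GRCm38, matched by Ensembl identifier for 24179 of the 25941 genes (93.2%) and for 14075 of the 14451 genes tested (97.4%). No coordinate was taken from that build. The GC slope of a library is the slope of its log2 CPM deviation from the mean of all libraries on GC fraction, over genes with an average log2 CPM above 3. For the GC correction, a smooth trend of the same kind was removed from each library through offsets in the edgeR model. This correction was added after the data had been seen. The same holds for leaving out control 6 and rofecoxib 2. Control 6 had the highest white and brown fat scores of all libraries, and rofecoxib 2 the highest cardiac muscle score. Control 6 also had the highest nerve score among controls, but celecoxib 7 had a higher one. Also added then were the nerve and immediate early score covariates and the fits with GC correction and a brown adipocyte, skeletal muscle or nerve score together.

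The alternatives fixed in advance were DESeq2 size factors, library totals alone, other low-count filters, the DESeq2 1.42.0 Wald test, limma-voom with sample quality weights, fits of only the 2 groups compared, a replicate block, marker scores as covariates, 2 surrogate variables from sva 3.50.0, and each library left out in turn. Pairs of libraries of a group were compared with a chi-square test of their counts. The chi-square per gene was 7.55 or more for every pair, so no pair lay within sampling noise and all 24 libraries were used.

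The edgeR step was tested on simulated counts in which a fixed set of genes was changed. At a fold of 1.25 it called 52% of the changed genes for celecoxib against control, 58% for rofecoxib against control and 56% for celecoxib against rofecoxib, with 14381, 14377 and 14381 genes tested. At a fold of 1.5 it called 96%, 94% and 98%, in the same order. The unchanged genes called were 10, 3 and 12. With a simulated GC trend like that of these libraries, 301 unchanged genes were called for celecoxib against rofecoxib and 6 after the GC correction. For rofecoxib against control these numbers were 65 and 12, and for celecoxib against control 6 and 9. The simulated spread was estimated from these libraries without GC correction, so it already held their GC variation within groups. The unchanged genes called under a GC trend may therefore be understated.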

Results

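The series measured gene expression by polyA RNA-seq in the thoracic aorta of male C57BL/6 mice that ate chow with celecoxib, chow with rofecoxib or plain chow for 3 weeks. Each group had 8 libraries, and library totals ran from 21652432 to 21687906 counts. Both drugs are inhibitors selective for the inducible cyclooxygenase, the product of Ptgs2. Celecoxib is a diarylpyrazole with a sulfonamide group and rofecoxib a diarylfuranone with a methylsulfone group. Their doses differed, at 100 mg/kg/day for celecoxib and 50 mg/kg/day for rofecoxib. The design compares each drug with control chow, and the drugs with each other.

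Libraries of a group correlated at Pearson's r of 0.962 to 0.994 over genes, on log2 CPM, and the common biological coefficient of variation was 0.16. The first principal component held 25.2% of the variance and the second 13.0%. Libraries also differed in how expression varied with transcript GC content. The GC slope, in log2 CPM per unit GC fraction, averaged 0.79 ± 0.93 with celecoxib, -1.14 ± 1.05 with rofecoxib and 0.35 ± 0.87 in controls (SD, n = 8 each). By two-sided exact permutation tests, the slope differed between the drugs (p = 0.00171, adjusted p = 0.0342). It did not pass between rofecoxib and control (exact p = 0.00622, adjusted p = 0.137) or between celecoxib and control (exact p = 0.332, adjusted p = 0.573). Across genes, which are not independent replicates, fold changes for rofecoxib against control nevertheless followed GC content (Spearman's rho -0.57 over 9864 genes). The rho was 0.62 for celecoxib against rofecoxib and 0.21 for celecoxib against control. Counts of called genes are therefore given with and without GC correction.

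**Figure D1:**
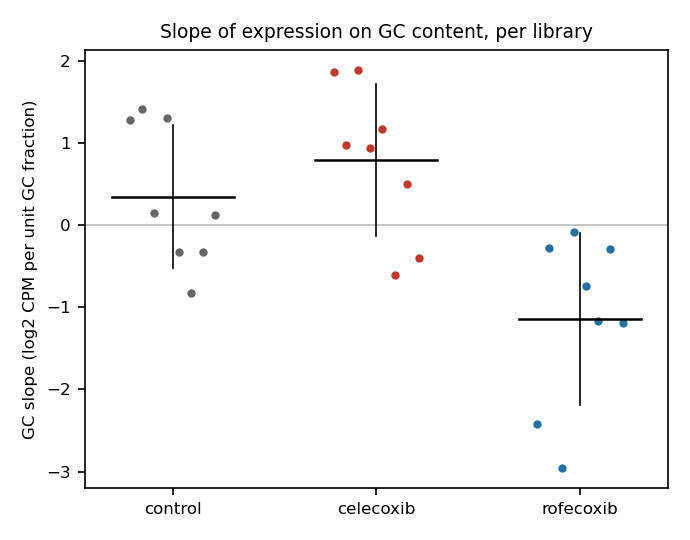
Slope of expression on transcript GC content, in log2 CPM per unit GC fraction, for each of the 24 libraries by group; points are libraries with random horizontal spread, horizontal bars are group means and vertical bars 1 SD. All 8 rofecoxib libraries lie below 0, from -2.96 to -0.09, while celecoxib libraries lie between -0.61 and 1.89 and control libraries between -0.83 and 1.42.

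With celecoxib, the genes called higher than in control aortas included glucocorticoid-responsive genes, chaperones of the endoplasmic reticulum and contractile genes of smooth muscle, and those called lower included lipid synthesis enzymes. In edgeR's quasi-likelihood test, 204 of 14451 genes were called, 132 higher and 72 lower, with a median absolute log2 fold change of 0.34 and 33 genes past 1.5-fold. Mthfd2, a mitochondrial enzyme of folate metabolism (ENSMUSG00000005667, mm9 chromosome 6 from 83255483 to 83267802), rose from 12.8 ± 2.53 to 22.9 ± 3.87 CPM (SD, n = 8 each; log2 fold change 0.84 ± 0.13, edgeR adjusted p = 0.0055). All 8 celecoxib libraries exceeded the control mean. Itga5, an integrin subunit that binds fibronectin, rose from 682 ± 76.1 to 1042 ± 152 CPM (log2 fold change 0.61 ± 0.10, edgeR adjusted p = 0.0101, higher in 8 of 8). Hif3a rose from 5.21 ± 1.82 to 11.1 ± 3.98 CPM (log2 fold change 1.09 ± 0.24, edgeR adjusted p = 0.0243, higher in 8 of 8). In 2 of 24 fits with 1 library left out Hif3a was not called, with an edgeR adjusted p of 0.0686 without celecoxib 5.

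Among 24 glucocorticoid-responsive genes tested, 7 rose and none fell, and 11 rose when adjusted over the list alone. The list passed camera with a median log2 fold change of 0.36 (adjusted p = 5.67e-09, and adjusted p = 0.370 with an estimated correlation). Its called members included Hif3a, Nfkbia, an inhibitor of NF-kB (0.53 ± 0.10), and Gadd45g (0.54 ± 0.12). Of 27 genes of the unfolded protein response, 3 rose, and 8 rose and 1 fell when adjusted over the list alone (camera adjusted p = 8.52e-05, and adjusted p = 0.404 with an estimated correlation). Those called were Hspa5, the main chaperone of the endoplasmic reticulum, from 490.3 ± 23.9 to 609.9 ± 63.1 CPM, Xbp1 (log2 fold change 0.30 ± 0.06) and Manf (0.40 ± 0.09). Smooth muscle markers had 5 of 20 members higher, 7 when adjusted over the list alone, with a median of 0.16 (camera adjusted p = 1.08e-06, and adjusted p = 0.404 with an estimated correlation). They included Actg2, from 291.5 ± 30.2 to 405.5 ± 47.8 CPM, Tpm1 (0.25 ± 0.06), Acta2 (0.30 ± 0.07) and Tagln (0.24 ± 0.06). With 1 library left out in turn, the call of Gadd45g was lost in 2 of 24 fits, that of Manf in 4, that of Tpm1 in 7, that of Acta2 in 10 and that of Tagln in 13.

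Fatty acid and triglyceride synthesis genes had 3 of 22 members called, all lower, and 16 lower when adjusted over the list alone, with a median log2 fold change of -0.73 (camera adjusted p = 7.83e-10, and adjusted p = 0.537 with an estimated correlation). Fasn, the fatty acid synthase, was at 272 ± 98.4 CPM against 836 ± 910.5 in controls (log2 fold change -1.62 ± 0.41, edgeR adjusted p = 0.0464, lower in 8 of 8). Scd1, which makes fatty acids unsaturated, was at 519 ± 262 against 1981 ± 2676 CPM (-1.93 ± 0.49, edgeR adjusted p = 0.0477, lower in 8 of 8). Control 6 had 8525 CPM for Scd1, against 408 to 1595 in the other 7 controls, and a white and general adipocyte marker score of 7.33 against 4.54 to 6.46. These 7 controls also lay below the control mean of Scd1, so lower in 8 of 8 says little there. For Fasn too the control mean of 836 CPM had a wide SD of 910.5, so its 8 of 8 is weak as well. Without control 6, Fasn was at -0.95 (edgeR adjusted p = 0.0727) and Scd1 at -1.01 (edgeR adjusted p = 0.0876), so neither was called, while Me1, a source of NADPH, moved from -0.73 to -0.44 and stayed called (edgeR adjusted p = 0.0195). Over the removal of each library in turn, the calls of Scd1 and Me1 were lost in 21 of 24 fits and that of Fasn in 22. Cholesterol synthesis genes had no called member and 1 lower when adjusted over the list alone (median -0.19, camera adjusted p = 8.52e-05, and adjusted p = 0.537 with an estimated correlation). Brown adipocyte markers had a median of -0.51 with no called member and 1 of 19 lower when adjusted over the list alone (camera adjusted p = 2.56e-05, and adjusted p = 0.600 with an estimated correlation). Fatty acid oxidation genes (median -0.41 over 33, camera adjusted p = 0.000285, and adjusted p = 0.838 with an estimated correlation) and oxidative phosphorylation genes (median -0.20 over 50, camera adjusted p = 4.13e-07, and adjusted p = 0.838 with an estimated correlation) had no called member by either adjustment. Without control 6 the fatty acid oxidation list had a camera adjusted p of 0.136.

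NRF2 antioxidant genes had 3 of 26 members lower, 7 when adjusted over the list alone, with a median of -0.12 (camera adjusted p = 9.06e-05, and adjusted p = 0.537 with an estimated correlation). The score of this list was 7.31 in control 6 against 6.59 to 6.89 in the other controls, and without control 6 the camera adjusted p was 0.00154. The called members were Nqo1 (-0.33 ± 0.07), Gclm (-0.16 ± 0.04) and Me1, which the lipid synthesis list also holds. Cytosolic ribosomal protein genes had no called member and 8 of 49 higher when adjusted over the list alone (median 0.10, camera adjusted p = 8.59e-14, and adjusted p = 0.537 with an estimated correlation). Cell cycle genes had none by either adjustment (median -0.12 over 32, camera adjusted p = 0.00449, and adjusted p = 0.781 with an estimated correlation). Immediate early genes had no called member, and 1 higher and 3 lower of 26 when adjusted over the list alone (median -0.16, camera adjusted p = 0.0442, and adjusted p = 0.838 with an estimated correlation). The camera adjusted p of this list was over the threshold without control 1 (0.193), control 2 (0.277), control 3 (0.0842), control 4 (0.0802), celecoxib 1 (0.0526), celecoxib 4 (0.114), celecoxib 5 (0.107), celecoxib 6 (0.129), rofecoxib 1 (0.0678), rofecoxib 6 (0.063) or rofecoxib 7 (0.0539). Outside the passing lists, Nr3c2, the mineralocorticoid receptor, was lower by -0.61 ± 0.14, and Sfrp4, a secreted antagonist of Wnt signalling, by -0.73 ± 0.15. The call of Nqo1 was lost in 2 of 24 such fits, that of Nr3c2 in 9 and that of Gclm in 17. Markers of Schwann cells and nerve had a median of 0.52 with none of 21 members called by either adjustment (camera adjusted p = 0.000759, and adjusted p = 0.838 with an estimated correlation), and without celecoxib 7 the camera adjusted p was 0.0547. Ptgs2, the target of the drug, was at 20.9 ± 4.05 CPM against 36.6 ± 16.7 in controls and was not called (log2 fold change -0.81 ± 0.23, edgeR adjusted p = 0.0696). Controls 1 to 8 had 47.0, 62.4, 50.0, 42.9, 26.7, 19.7, 13.3 and 31.1 CPM, and the celecoxib libraries lay between 13.9 and 25.6 CPM. Without control 6 and rofecoxib 2 it was called (-0.90, edgeR adjusted p = 0.0434). Ptgs1, which encodes the constitutive cyclooxygenase (-0.03, edgeR adjusted p = 0.921), the prostacyclin synthase gene Ptgis (0.26, edgeR adjusted p = 0.0879) and Nos3 of the endothelium (0.35, edgeR adjusted p = 0.251) were not called.

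Scores of brown adipocyte and skeletal muscle markers differed from control by -0.60 (exact permutation p = 0.0862, adjusted p = 0.383) and 0.15 (exact permutation p = 0.0208, adjusted p = 0.156). With the brown adipocyte score as a covariate 7 genes were called and with the skeletal muscle score 11, or 18 and 20 with GC correction as well.

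After GC correction 304 genes were called for celecoxib against control, 210 higher and 94 lower, and these held 182 of the 204; 42 of 100 splits of the libraries, the real one included, had at least 13 passing lists; without control 6 and rofecoxib 2 the count was 231, 116 higher and 115 lower, without control 6 alone 264, 134 higher and 130 lower, and with library totals in place of TMM factors it was 183, 100 higher and 83 lower. The count of 204 fell to 42 without celecoxib 5, 57 without celecoxib 4, 73 without celecoxib 8, 93 without celecoxib 3, 135 without celecoxib 7, 64 without control 2, 68 without control 3, 96 without control 1, 109 without control 7, 113 without control 8, 116 without control 4 and 135 without rofecoxib 3, and it was 312 without celecoxib 2.

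With rofecoxib, the genes called lower than in control aortas included fibroblast, extracellular matrix and macrophage genes, and those called higher included contractile genes of smooth muscle and ribosomal protein genes. In edgeR's quasi-likelihood test 766 of 14451 genes were called, 351 higher and 415 lower, with a median absolute log2 fold change of 0.27 and 64 genes past 1.5-fold. Podn, a small proteoglycan of the matrix (ENSMUSG00000028600, mm9 chromosome 4 from 107687194 to 107705144), fell from 117.1 ± 13.0 to 73.2 ± 10.4 CPM (SD, n = 8 each; log2 fold change -0.68 ± 0.09, edgeR adjusted p = 0.000809, lower in 8 of 8). Pcolce, which enhances procollagen processing, fell from 248 ± 31.2 to 163 ± 18.5 CPM (-0.60 ± 0.09, edgeR adjusted p = 0.000809, lower in 8 of 8). Col1a1, a chain of type I collagen (ENSMUSG00000001506, mm9 chromosome 11 from 94797336 to 94814558), fell from 2392 ± 483 to 1519 ± 243 CPM (-0.65 ± 0.13, edgeR adjusted p = 0.0119, lower in 8 of 8). These calls held after GC correction, with edgeR adjusted p-values of 0.0022 for Podn, 0.013 for Pcolce and 0.031 for Col1a1.

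Of 20 markers of fibroblasts and adventitia, 6 fell and none rose, and 9 fell when adjusted over the list alone, with a median of -0.25 (camera adjusted p = 9.41e-06, and adjusted p = 0.747 with an estimated correlation). After GC correction 1 of these markers was called lower, while the median was -0.27 and the list passed camera (adjusted p = 2.24e-06, and adjusted p = 0.614 with an estimated correlation). Of 49 extracellular matrix genes, 6 fell, and 12 fell when adjusted over the list alone, with a median of -0.14 (camera adjusted p = 0.00011, and adjusted p = 0.747 with an estimated correlation). After GC correction 3 of this list were called lower and the median was -0.07. Both lists hold Fbln1, a matrix glycoprotein that fell by 0.57 on the log2 scale. It was not called without control 7 (edgeR adjusted p = 0.0506) or after GC correction (edgeR adjusted p = 0.051). Timp1, an inhibitor of metalloproteinases, was at -0.41 ± 0.10, and its call, like that of Fbln1, was lost in 2 of 24 fits with 1 library left out. Macrophage and monocyte markers had 3 of 22 members lower, 8 when adjusted over the list alone (median -0.36, camera adjusted p = 0.000338, and adjusted p = 0.747 with an estimated correlation). These were Cd14 (-0.65 ± 0.17), C1qc (-0.55 ± 0.15) and Fcer1g (-0.50 ± 0.15), whose calls were lost in 6, 11 and 18 of 24 fits with 1 library left out. After GC correction their log2 fold changes were -0.60 ± 0.17, -0.44 ± 0.16 and -0.47 ± 0.15, and none was called (edgeR adjusted p-values of 0.0674, 0.143 and 0.092). The list had a median of -0.32 there and passed camera (adjusted p = 2.66e-05, and adjusted p = 0.614 with an estimated correlation).

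Smooth muscle markers had 4 of 20 members higher, 9 when adjusted over the list alone (median 0.17, camera adjusted p = 0.000143, and adjusted p = 0.747 with an estimated correlation), among them Tagln (0.26 ± 0.06). Of 49 cytosolic ribosomal protein genes, 9 rose and none fell, and 17 rose when adjusted over the list alone (median 0.08, camera adjusted p = 1.68e-07, and adjusted p = 0.747 with an estimated correlation). Rpl30 (0.17 ± 0.03) and Rps18 (0.18 ± 0.04) were among them. After GC correction Rpl30 was at 0.09 ± 0.04 and not called (edgeR adjusted p = 0.223), while 7 of the list were called higher with a median of 0.10. Fatty acid and triglyceride synthesis genes had 3 of 22 members lower, 14 when adjusted over the list alone (median -0.56, camera adjusted p = 0.00011, and adjusted p = 0.747 with an estimated correlation). Fasn was at 309.6 ± 99.5 CPM against 836 ± 910.5 (log2 fold change -1.43 ± 0.40, edgeR adjusted p = 0.0445), and without control 6 at -0.76 (edgeR adjusted p = 0.111), with the call lost in 13 of 24 such fits and after GC correction (edgeR adjusted p = 0.0981), when 1 member of the list was called. Srebf1, a transcription factor that drives lipid synthesis genes, fell by 0.51 on the log2 scale (edgeR adjusted p = 0.0147). NRF2 antioxidant genes had 2 of 26 members lower, 3 when adjusted over the list alone (median -0.10, camera adjusted p = 0.00332, and adjusted p = 0.747 with an estimated correlation), Osgin1 (-0.67 ± 0.12) and G6pdx (-0.30 ± 0.07). Without control 6, G6pdx was at -0.20, and without control 7 it was not called (edgeR adjusted p = 0.0545). Oxidative phosphorylation genes had no called member by either adjustment (median -0.15, camera adjusted p = 0.036, and adjusted p = 0.852 with an estimated correlation). The camera adjusted p of this list was 0.467 without control 6, 0.0813 without rofecoxib 5, 0.0793 without rofecoxib 4, 0.0792 without rofecoxib 6, 0.0596 without control 8 and 0.0511 without celecoxib 4.

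Ptgs2 with rofecoxib was at 43.7 ± 7.46 CPM against 36.6 ± 16.7 in controls and was not called (log2 fold change 0.26 ± 0.22, edgeR adjusted p = 0.471). Ptgs1 (-0.08, edgeR adjusted p = 0.746), Ptgis (-0.04, edgeR adjusted p = 0.769), Ptges (-0.52, edgeR adjusted p = 0.0825) and the prostacyclin receptor gene Ptgir (-0.42, edgeR adjusted p = 0.0983) were not called either. Ptger1, a receptor gene for prostaglandin E, was lower (-0.25 ± 0.07, edgeR adjusted p = 0.0454). It was not called after GC correction (edgeR adjusted p = 0.14) or in 12 of 24 fits with 1 library left out. Actc1, the cardiac actin gene, had the largest fold among the called genes named here (2.16 ± 0.56, edgeR adjusted p = 0.0333). Without rofecoxib 2, in which it stood at 89.1 CPM against 3.467 to 14.1 in the other 7 rofecoxib libraries, it was at 1.02 and not called (edgeR adjusted p = 0.0779). The call of Actc1 was lost in 6 of 24 fits with 1 library left out, also without control 6 (2.13, edgeR adjusted p = 0.0619).

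The skeletal muscle marker score was 2.30 ± 0.14 with rofecoxib and 2.13 ± 0.15 in controls (SD, n = 8 each, exact permutation p = 0.0311, adjusted p = 0.178). With it as a covariate 12 genes were called, and 1 with GC correction as well.

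After GC correction 175 genes were called for rofecoxib against control, 87 higher and 88 lower, and these held 134 of the 766; 85 of 100 splits, the real one included, had at least 8 passing lists; without control 6 and rofecoxib 2 the count was 215, 77 higher and 138 lower, and with both changes 85. The count of 766 fell to 170 without control 7, 178 without control 5, 335 without control 6, 435 without control 8, 179 without rofecoxib 8, 199 without rofecoxib 7, 401 without rofecoxib 2 and 479 without rofecoxib 1.

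Between the drugs, the genes called higher with celecoxib included matrix, fibroblast, glucocorticoid-responsive and unfolded protein response genes, and those called lower included immediate early genes and Ptgs2. In edgeR's quasi-likelihood test 3275 of 14451 genes were called, 1661 higher and 1614 lower with celecoxib, with a median absolute log2 fold change of 0.27 and 274 genes past 1.5-fold. Fkbp5, a co-chaperone of steroid receptors (ENSMUSG00000024222, mm9 chromosome 17 from 28535838 to 28654671), was at 197 ± 34.3 CPM with celecoxib and 87.0 ± 36.6 with rofecoxib (SD, n = 8 each; log2 fold change 1.18 ± 0.27, edgeR adjusted p = 0.00579, higher in 8 of 8). Atf3, a stress-induced transcription factor (ENSMUSG00000026628, mm9 chromosome 1 from 192993973 to 193007421), was at 56.1 ± 27.4 and 187 ± 44.3 CPM (-1.74 ± 0.38, edgeR adjusted p = 0.00386, lower in 8 of 8). Ptgs2 (ENSMUSG00000032487, mm9 chromosome 1 from 151947052 to 151955342) was at 20.9 ± 4.05 and 43.7 ± 7.46 CPM (-1.06 ± 0.23, edgeR adjusted p = 0.00348, lower in 8 of 8), with a 95% interval of the difference from -1.53 to -0.59.

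**Figure D2:**
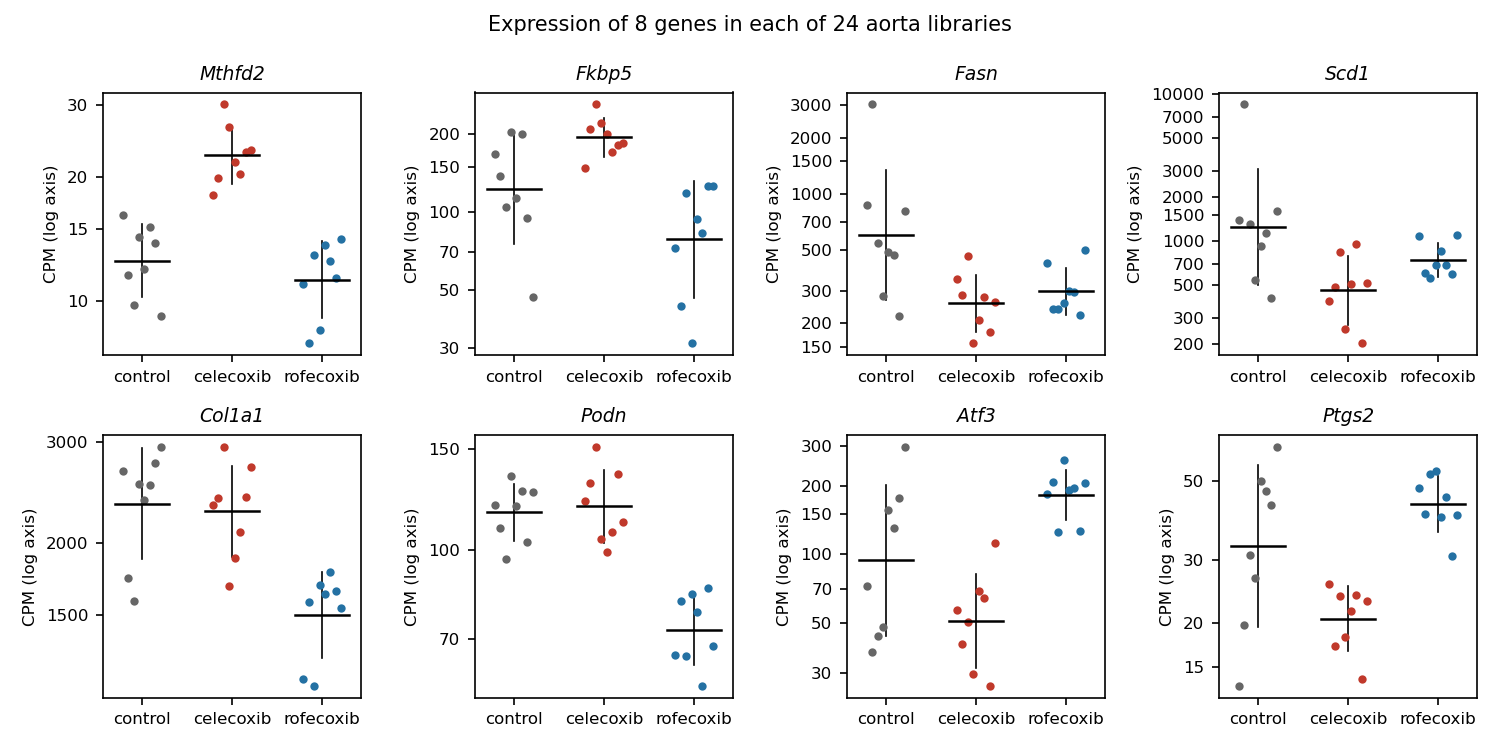
Expression of 8 genes in CPM on a log axis, 1 panel per gene, for the 8 libraries of each group; points are libraries with random horizontal spread, and bars are the mean and SD of log2 CPM drawn back on the CPM axis. Ptgs2 lies between 13.9 and 25.6 CPM in celecoxib libraries and between 30.9 and 53.4 CPM in rofecoxib libraries, while Fasn reaches 3019 CPM in 1 control library.

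Of the 20 fibroblast markers 9 were higher with celecoxib than with rofecoxib, and 9 when adjusted over the list alone (median 0.29, camera adjusted p = 5.95e-05, and adjusted p = 0.982 with an estimated correlation), and 5 were called higher after GC correction. Of 49 extracellular matrix genes 18 were higher and 1 lower, and 18 higher and 2 lower when adjusted over the list alone (median 0.17, camera adjusted p = 8.54e-05, and adjusted p = 0.982 with an estimated correlation). After GC correction 7 were higher and none lower, and the median was 0.08. Col1a1 of the matrix list was higher by 0.60 ± 0.13, and Serpinf1 and Pcolce of the fibroblast list by 0.61 ± 0.12 and 0.47 ± 0.09. Podn, in neither list, was higher by 0.72 ± 0.09. Of 24 glucocorticoid-responsive genes 11 were higher and 1 lower, and 13 and 1 when adjusted over the list alone (median 0.33, camera adjusted p = 0.00238, and adjusted p = 0.982 with an estimated correlation), including Fkbp5 and Fam107a (0.68 ± 0.15). After GC correction 5 of this list were higher and 1 lower. Of 27 unfolded protein response genes 12 were higher and 1 lower, and 12 and 2 when adjusted over the list alone (median 0.15, camera adjusted p = 0.00258, and adjusted p = 0.982 with an estimated correlation), including Sdf2l1 (0.74 ± 0.12) and Pdia6 (0.23 ± 0.04). The member that was lower was Atf3, which the immediate early list also holds. The unfolded protein response list had 12 higher and 2 lower after GC correction, with a median of 0.19. Camera then gave it an adjusted p of 2.22e-05, and an adjusted p of 0.958 with an estimated correlation.

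Of 26 immediate early genes 10 were lower with celecoxib and none higher, and 10 lower and 3 higher when adjusted over the list alone (median -0.25, camera adjusted p = 0.0421, and adjusted p = 0.982 with an estimated correlation). Cyr61 (-1.14 ± 0.26) and Jun (-0.94 ± 0.22) were among them. The camera adjusted p of this list was over the threshold without celecoxib 1 (0.0548), celecoxib 2 (0.0601), celecoxib 4 (0.072), celecoxib 5 (0.0912), celecoxib 6 (0.0888), rofecoxib 2 (0.0686), rofecoxib 4 (0.112), rofecoxib 5 (0.151) or rofecoxib 6 (0.0718), and without control 6 and rofecoxib 2 together (0.0589). The immediate early list had 10 lower and none higher after GC correction, with a median of -0.37. Camera then gave it an adjusted p of 2.22e-05, and an adjusted p of 0.971 with an estimated correlation. The heat shock genes Dnajb1 (-1.12 ± 0.25) and Hspa1a were also lower with celecoxib. Calls after GC correction are not given here for Fkbp5, Atf3, Sdf2l1, Pdia6, Cyr61, Jun or Dnajb1. Mthfd2 was higher with celecoxib (0.99 ± 0.13, edgeR adjusted p = 0.000298), and Nr3c2 was lower (-0.64 ± 0.14). The cardiac muscle gene Mb had a log2 fold change of -3.34, which was -0.01 without rofecoxib 2 (edgeR adjusted p = 0.992).

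Beside Ptgs2, the prostanoid genes Ptgis, Ptger1 and Tbxa2r, the thromboxane receptor gene, and Nos3 were called between the drugs, and these 4 not after GC correction. Ptgis was higher with celecoxib by 0.30 ± 0.08 (edgeR adjusted p = 0.0094, and 0.18 after GC correction) and Nos3 by 0.46 (edgeR adjusted p = 0.0399, and 0.20 after GC correction), whose call was also lost in 11 of 24 fits with 1 library left out. Ptger1 was higher by 0.28 ± 0.07 (edgeR adjusted p = 0.0104, and 0.109 after GC correction) and Tbxa2r by 0.30 ± 0.08 (edgeR adjusted p = 0.0149, and 0.722 after GC correction). For several genes no difference between the drugs was called, and the 95% intervals of celecoxib minus rofecoxib were -0.24 to 0.33 for Ptgs1, -0.14 to 0.11 for Tagln, -0.11 to 0.19 for Acta2, -1.01 to 0.64 for Fasn and -1.56 to 0.41 for Scd1.

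After GC correction 1325 genes were called between the drugs, 712 higher and 613 lower with celecoxib, and these held 1014 of the 3275; 93 of 100 splits, the real one included, had at least 5 passing lists. The count was 2147 without rofecoxib 8, 3192 without control 6 and rofecoxib 2, and 1810 with the immediate early score as a covariate.

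Both drug comparisons called 18 genes in the same direction, 12 higher and 6 lower, and none in opposite directions. Independent lists of these sizes would share 3.21 higher and 2.07 lower genes. The 2 comparisons are not independent, as the shared controls alone push their fold changes the same way (simulated r 0.51). These expected numbers are therefore too low as a baseline. In 20 simulations of unchanged groups against the same controls no gene was shared. In none of them did both comparisons call genes in the same direction, so none could be shared. The higher genes included Tagln, Tpm1, Acta2, Actg2 and Csrp1 of smooth muscle and Anxa5, and the lower genes included Fasn, Sfrp4, Igfbp5 and Ccdc85a. Csrp1, Anxa5 and Igfbp5 were chosen after their values had been seen. The smooth muscle marker score was higher by 0.16 with celecoxib (exact permutation p = 0.0205, adjusted p = 0.156). With rofecoxib it was also higher by 0.16 (exact permutation p = 0.00684, adjusted p = 0.137). A different share of smooth muscle in the samples was not tested apart from a change per cell. With 1 library left out in turn, 4 to 17 of the 18 stayed called with both drugs, the fewest without control 7, and only Sfrp4 and 3110003A17Rik did so in all 24 fits. The call with either drug was lost in 16 fits for Acta2 and Anxa5, 13 for Tagln, 12 for Csrp1, 8 for Tpm1, 6 for Actg2, 23 for Fasn, 4 for Ccdc85a and 1 for Igfbp5. None of the 18 differed between the drugs in edgeR's test. Picking genes called the same way with both drugs favours similar changes, so this says little about an equal response. The smallest edgeR adjusted p was 0.0573, for Ccdc85a (-0.53 with celecoxib and -0.31 with rofecoxib). Across genes, which are not independent replicates, Pearson's r of the fold changes was 0.41 against a simulated 0.51, and the covariance was 0.0226 against a simulated 0.0149. When the controls were split into 4 and 4, each of the 20 splits shared 0 genes. Independent lists would have shared at most 1.22 lower and 0.0789 higher genes there. The median r was 0.14 (-0.07 to 0.33) and the median covariance 0.0169 (-0.011 to 0.032). The simulated covariance came from shared controls, so it is no baseline for these splits. After GC correction 15 genes were shared, and by the DESeq2 Wald test 75, with 1 in opposite directions.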

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

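The tests of GC content, tissue and cell shares and single libraries below were chosen after the results they bear on had been seen, except the within-group test of the GC trend and the splits of the libraries. The requirement that a marker score itself be lower, in the fibroblast tests, was added after the values had been seen.

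The first pattern is the 3275 genes that edgeR called between celecoxib and rofecoxib, whose fold changes followed transcript GC content (Spearman's rho 0.62 over 9864 genes, across genes, which are not independent replicates). The calls lost to the correction fell from a median absolute log2 fold change of 0.24 to 0.12 while their median SE went from 0.07 to 0.06, so the smaller difference ended them. Of these 2261 genes, 93.5% varied within groups with the GC slope of the library in the direction of the group difference, against 67.4% of genes not called. A GC trend may account for them, but 88.9% of the kept calls varied so too, so this test does not separate kept from ended calls. The slope was itself fitted on gene levels in these libraries, and the fold changes followed GC content. A high share was therefore partly built in. The trend that was removed is not the whole cause of the 1014 calls that stayed in the same direction. With a brown fat, skeletal muscle or nerve score as a covariate, at least 2734 of the 3275 stayed called. The muscle and nerve scores differed little between the drugs (exact permutation p = 0.874 and 0.734), so these covariates could test little. The fibroblast score differed more (0.32, exact permutation p = 0.0073, adjusted p = 0.0539) and was not tried as a covariate, so tissue share stays open. With the immediate early score 1596 of the 3275 stayed. Of the 1014, 776, 898 and 982 stayed with GC correction and the brown, muscle or nerve score together, and the others stay open. The library day is not given per library, so a day shared by libraries of 1 group stays open for both parts. An effect of the drugs stays open too and was not tested apart from it. Fold changes for rofecoxib against control also followed GC content (Spearman's rho -0.57 over 9864 genes across genes). There the correction kept 134 of the 766 calls, and whether a GC trend accounts for the others was not tested.

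The second pattern is the lower fatty acid and triglyceride synthesis list with each drug, beside a control 6 that stood far above the other controls. The list passed camera at the preset correlation whichever library was left out. The highest camera adjusted p was 1.73e-07 for celecoxib and 0.00121 for rofecoxib, both without control 6. It also passed after GC correction (camera adjusted p = 2.19e-10 and 1.43e-05). So neither 1 library nor the GC trend alone made these camera calls, but camera also passed many lists in other splits. The score itself differed by -0.56 with celecoxib (exact permutation p = 0.0235, adjusted p = 0.156). With rofecoxib it differed by -0.43 (exact permutation p = 0.0732, adjusted p = 0.366), so neither difference passed. With celecoxib the synthesis score was lower by more than the white and general adipocyte score (difference -0.43, exact permutation p = 0.0028), which argues against a smaller share of fat cells, but not by more than the brown adipocyte score (0.037, exact permutation p = 0.834), so a smaller share of brown fat cannot be told apart. With rofecoxib it was the other way round, with -0.22 against the white and general score (exact permutation p = 0.231) and -0.25 against the brown score (exact permutation p = 0.019), so that a smaller share of fat cells stays open there. Camera with an estimated correlation did not pass for this list, and 6 of 100 splits for celecoxib and 29 for rofecoxib gave it a p as small, so chance could not be excluded for either drug.

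The third pattern is the lower extracellular matrix list with rofecoxib. The list passed camera after GC correction both against control (adjusted p = 0.00362) and against celecoxib (adjusted p = 0.00292), so the GC trend is not the whole cause of these calls, although the median log2 fold change went from -0.14 to -0.07 and, with celecoxib minus rofecoxib, from 0.17 to 0.08, and they were lost with an estimated correlation (adjusted p = 0.677 and 0.971 after GC correction, 0.747 and 0.982 without it). The fibroblast score was lower too, by -0.28 against control (exact permutation p = 0.0132, adjusted p = 0.148) and by -0.32 against celecoxib (exact permutation p = 0.0073, adjusted p = 0.0539), and the matrix score was not lower by more (differences 0.15, exact permutation p = 0.142, and 0.16, exact permutation p = 0.108). Without the 5 genes that both lists hold, the differences were 0.18 (exact permutation p = 0.127) and 0.19 (exact permutation p = 0.0884). A smaller share of adventitial fibroblasts in the rofecoxib samples is thus compatible with these values, and a lower output per fibroblast was not tested apart from it. For the camera calls, 19 and 11 of 100 splits gave the list a p as small, so chance could not be excluded. The matrix score itself passed for celecoxib minus rofecoxib (0.16, exact permutation p = 0.000622, adjusted p = 0.0249). For rofecoxib against control it did not pass (-0.13, exact permutation p = 0.0194, adjusted p = 0.155). These scores were not corrected for GC content.

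Other splits of the libraries were set against each count. Few splits called as many genes as the real one, which makes chance unlikely for these counts but does not exclude it. For celecoxib against control 2 of 100 splits, the real one included, called as many (204, highest other 401). It was 1 for rofecoxib against control (766, highest other 530) and 1 for celecoxib against rofecoxib (3275, highest other 2979). Such splits cannot tell a batch that follows the groups from an effect of the drugs. The splits with 401, 530 and 2979 calls placed 10, 10 and 12 of 16 libraries as the real groups do, where 8 is the least possible, and why they called so many genes was not tested. Chance cannot be excluded for the number of lists passing camera, as 42 splits had as many as the 13 for celecoxib (highest other 21), 85 as many as the 8 for rofecoxib (highest other 23) and 93 as many as the 5 between the drugs (highest other 21). List by list, 100 splits drawn anew, the real one included, were set against each camera p, without adjustment over lists. With celecoxib 3 gave a p as small for the glucocorticoid and unfolded protein lists. It was 53 for oxidative phosphorylation, 52 for fatty acid oxidation, 47 for nerve and 45 for immediate early genes. With rofecoxib it was 85 for oxidative phosphorylation. The other passing lists had 6 to 34. For the 18 genes shared by both drug comparisons, 1 of 100 splits gave as many, the real one, and the highest other was 1; most of the splits above called no gene, so a low number of shared calls was to be expected and says nothing of the shared controls.

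In 28 of 432 groups of 8 values, 1 library stood apart from the other 7 by more than Dixon's 95% critical value, where chance gives about 21.6 (5%). Control 6 had 11 of them. Its scores, as mean log2 CPM, were 8.01 for fatty acid and triglyceride synthesis (other controls 5.83 to 6.82), 7.483 for oxidative phosphorylation (6.34 to 6.68), 7.31 for NRF2 genes (6.59 to 6.89), 6.75 for hypoxia and glycolysis (6.28 to 6.41), 3.32 for carbonic anhydrases (1.96 to 2.55) and 4.92 for haemostasis (5.24 to 5.38). Its levels were 8525 CPM for Scd1, 368.0 for Me1, 201.7 for Srebf1, 91.6 for G6pdx and, lower than the other controls, 22.2 for Nr3c2. Rofecoxib 2 had 4, with a cardiac muscle score of 5.83 (other rofecoxib libraries 2.41 to 3.30) and 89.1 CPM for Actc1, 43.1 for Mb and 24.5 for Ttn. Among the other libraries, control 4 had a TMM factor of 0.981 (other controls 1.005 to 1.018), celecoxib 2 a renin-angiotensin and endothelin score of 4.39 and celecoxib 8 a hypoxia and glycolysis score of 6.4724. The single genes, in CPM, were Ddo in rofecoxib 6 (25.1), Gadd45g in celecoxib 5 (111.8), Rbm3 in rofecoxib 1 (164.2, low), Rassf1 in rofecoxib 7 (21.5), Actc1 in control 3 (8.89), Gm22 in celecoxib 8 (7.81), Copg2 in rofecoxib 5 (32.7, low), Coq10b in celecoxib 4 (95.6, low), Apold1 in control 2 (19.1) and Dpep1 in celecoxib 4 (242.9).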

How the results depend on the processing

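The GC correction, leaving out control 6 and rofecoxib 2, the nerve and immediate early covariates, and GC correction with a marker score were chosen after seeing the data; the other settings were planned. Counts of called genes are for celecoxib against control (main count 204), rofecoxib against control (766) and celecoxib against rofecoxib (3275). Counts under settings not given in this section stayed within 1.5 times of these. Without a low-count filter the first 2 were 86 and 294, with more genes to adjust over, and with fits of only the 2 groups 88 and 461, with fewer libraries behind the spread. The DESeq2 Wald test gave 479 and 1594, and limma-voom with quality weights 621 for the first. With a skeletal muscle score they were 11 and 12, with a brown adipocyte score 7 for the first, with 2 surrogate variables 2084 and with a nerve score 1774 for the second, and with an immediate early score 56 for the first and 1810 for the last. GC correction gave 175 for the second and 1325 for the last. Without control 6 and rofecoxib 2 the second was 215, and with GC correction as well the 3 were 340, 85 and 1346. GC correction with a brown adipocyte score gave 18, 165 and 1185, with a skeletal muscle score 20, 1 and 1162, and with a nerve score 461, 458 and 1403. The cause was not tested for these.

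With 1 library left out the counts ran from 42 to 312, from 170 to 1121 and from 2147 to 3739. After GC correction they ran from 66 to 436, from 44 to 374 and from 728 to 1777. The GC-corrected count moved by over 1.5 times for celecoxib against control without celecoxib 3 (158), 4 (119), 5 (66) and 8 (153) and control 2 (152), 3 (130) and 7 (177). For rofecoxib against control it did so without rofecoxib 1 (102), 2 (102), 3 (110), 7 (100) and 8 (64) and control 1 (88), 2 (282), 3 (84), 4 (374), 5 (68) and 7 (44). Between the drugs it did so without celecoxib 4 (858), 5 (848) and 8 (728) and rofecoxib 8 (764).

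The replicate numbers do not pair the samples: 10 of 24 same-numbered pairs had a correlation of deviations over 0.1, and 5 of 24 libraries correlated best with their own number. With the number as a replicate block the counts were 187, 653 and 3193, and with GC correction as well 342, 116 and 1402. The block changed no call of the 26 passing lists.

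Of 13, 8 and 5 passing lists, 0, 0 and 0 passed with an estimated correlation, and 3, 0 and 4 by fry's directional test, which does not compare a list with other genes. GC correction kept all 26 passing results. It gave 14 lists for rofecoxib against control, adding by camera the prostanoid (adjusted p = 0.0219), xenobiotic metabolism (0.0323) and fatty acid oxidation (0.0463) lists as lower and the immediate early (0.0117), nerve (0.0179) and skeletal muscle (0.0205) lists as higher, and between the drugs the brown adipocyte list (0.0183) as lower with celecoxib; none passed with an estimated correlation. The 18 genes shared by both drug comparisons became 0 with the controls split into 4 and 4, which leaves fewer controls per drug, and 75 by the DESeq2 Wald test.

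Among up to 230 results for single genes per setting, no call was reversed, and 66 calls were lost after GC correction, 89 with a skeletal muscle score and 60 with an immediate early score. The totals of the deposited counts were nearly equal, the sequencing depth before that step is unknown, and in simulated data 52%, 58% and 56% of genes with the smallest simulated fold were called, so small differences can be missed.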

Other observations

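The test of the relation between Ptgs2 and the immediate early genes was chosen after the levels had been seen.

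Lists that passed in no comparison without GC correction are given here with the smallest of their 3 camera adjusted p-values; after GC correction the prostanoid (0.0219), skeletal muscle (0.0205) and xenobiotic metabolism (0.0323) lists passed for rofecoxib against control. For rofecoxib against control these were xenobiotic metabolism (0.0793), prostanoid synthesis and receptors (0.092), interferon-stimulated genes (0.113), cardiac muscle (0.113), leukotriene pathway (0.128), B cells (0.128), renin-angiotensin and endothelin (0.198), white and general adipocytes (0.198), nitric oxide signalling (0.471), carbonic anhydrases (0.494), the circadian clock (0.618) and inflammatory cytokines (0.618). For celecoxib against control they were skeletal muscle (0.101), endothelium (0.156), erythrocytes (0.186), haemostasis (0.364), heat shock (0.445), TGF-beta (0.447), hypoxia and glycolysis (0.447), mesothelium (0.497) and neutrophils (0.557). The T cell and lung lists had under 5 genes tested.

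Ptgs2 is itself an immediate early gene in many cells, and the immediate early list was lower with celecoxib than with rofecoxib by camera at the preset correlation (adjusted p = 0.0421). That call was lost with an estimated correlation (adjusted p = 0.982), without control 6 and rofecoxib 2 (adjusted p = 0.0589) and in 9 of 24 fits with 1 library left out. The hypothesis was that Ptgs2 varies with these genes from library to library. With group means removed, Ptgs2 and the immediate early score correlated over 24 libraries (Pearson's r = 0.65, permutation p = 0.00464, adjusted p = 0.0148; Spearman's rho = 0.65, permutation p = 0.00349, adjusted p = 0.0159; 5 relations computed, 100000 permutations). Without control 2 and control 8, the libraries farthest from the median score, r was 0.60 (permutation p = 0.00591) and rho 0.64 (permutation p = 0.00638). Within groups of 8, r was 0.81 in controls (exact permutation p = 0.0137, adjusted p = 0.0171; rho 0.76, exact p = 0.0368), 0.89 with celecoxib (exact permutation p = 0.0102, adjusted p = 0.017; rho 0.67, exact p = 0.0831) and -0.16 with rofecoxib (exact permutation p = 0.70; rho -0.10, exact p = 0.84). In controls 1 to 8 the immediate early scores were 6.13, 6.42, 5.98, 5.99, 5.74, 5.55, 5.57 and 5.42. Their GC slopes were -0.83, 0.12, -0.33, -0.33, 1.31, 1.42, 1.28 and 0.15. Each of controls 1 to 4 thus had a higher score, more Ptgs2 and a lower GC slope than each of controls 5 to 8. The drugs differed in the same way, with mean slopes of 0.79 for celecoxib and -1.14 for rofecoxib. This split of the controls was seen after the values and was not tested. Libraries that shared a day or handling would also give a relation between Ptgs2 and the immediate early score. The day of each library is not given in the sources used here, so the source of the relation stays open. The relation of 0.65 over all libraries rests on controls and celecoxib libraries, and whether it differs from that with rofecoxib was not tested. Such genes can respond to tissue handling, so the lower Ptgs2 with celecoxib could reflect handling or a drug effect, which these data do not separate.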
